A study of Mus musculus with 6 samples.

How the data were processed

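Gene expression was measured in adult testes of C57BL/6 mice on the Illumina MouseRef-8 v2 BeadChip, a single-colour array of 50-base probes, with 1 array for each of 3 mice of room-air dams and 3 mice of smoke-exposed dams. Per the file headers, the deposited table of unprocessed values holds 1 intensity per probe and array, on a linear scale, for 25697 probes and without detection p-values. The authors also deposited a table of processed values on a log2 scale with a median of 7.87 in every column. Per the submitters' processing notes the lumi package was used, in a version not given in the sources used here, and the steps it ran are not given either. Each processed column followed the unprocessed intensity of its own array, with a correlation across probes of deviations from the probe mean of at least 0.859, against at most 0.243 for any other array. Its scale and direction are thus settled, and probes were not centred. The deposited comparison table holds, per the file headers, a p-value, a step-up adjusted p-value, a ratio and a signed fold of smoke over room air, with a p-value on 25553 lines. These were recomputed as a check: the deposited ratio equals the group difference of the processed values to within 7.3e-06 on the log2 scale, and the deposited p-value equals that of a plain comparison of the 2 groups with a pooled variance to within 5.1e-06 of its size. A further sheet of the deposited workbook was identical to the list of differential genes and was not used. No per-array column was left without a sample.

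Symbols came from the deposited comparison table, in which 103 of the 25697 probes had an emptied line. For 23692 probes the symbol was updated through the Entrez identifier with RefSeq's table for GRCm38.p6, and the array's own symbol was kept for the rest. In all, 25593 probes carried a symbol and 104 did not. Probe coordinates are those of the deposited table, whose genome build is not given in the sources used here. Only 7.66% of them lie inside the span of their gene in GRCm38, so the build differs, and no coordinate of that assembly is printed. The position of a probe in its transcript is the start base given in the same table, counted from the 5′ end.

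Intensities were corrected for background with normexp (saddle point, offset 50), quantile normalized and log2 transformed in limma 3.58.1 under R 4.3.3. Without detection p-values, the brighter 50% of the probes by mean unprocessed intensity over all 6 arrays were kept, which left 12848 probes with a mean of at least 158. Groups were compared with limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over the probes tested and a threshold of 0.05. A probe was taken as not above background in a group where it lay under the array's median intensity on all 3 arrays. For such a probe the change is given as a bound, at least N-fold, from the brighter group's mean to the mean of the higher of the array median and the probe's own value. The bound holds for the background-corrected values of this fit alone, since the size of a fold depends on the correction. The group means stay as measured.

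The 33 gene lists were tested with fry in limma, which asks whether the members of a list move on balance in 1 direction and compares them with no other genes. Each gene was represented by its probe of highest mean, 31 lists had at least 5 measured genes, and adjustment was by Benjamini-Hochberg over those 31. Lists were also tested with camera, with a preset correlation of 0.01 and with an estimated correlation. Gene lists, designs, named genes and the first set of alternatives were chosen before the data were examined. Named genes were the 10 with the largest change in each direction at an adjusted p under 0.05 with no overlap between groups. In each list, up to 4 members past the threshold, over all probes or adjusted over the list alone, were named, or the 2 of smallest p. The rule also took the 5 highest and 5 lowest folds of the deposited list, the genes that check the labels, and Cyp1a1, Cyp1b1, Ahrr and Tiparp. Some members that this rule takes are not reported here. Other genes named below were chosen after their values were seen.

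The pipeline was tested on simulated intensities for the comparison of room air with smoke over 12848 tested probes. With 50 probes changed at each size, it recovered 6 at the smallest size, under 1.5-fold, 43 at 1.5-fold, 47 at 2-fold and 48 at 3-fold. It called 6 of 12648 unchanged probes, and none of 12848 where no change was simulated. Errors were drawn independently for each probe, with no difference shared across an array or by probe position. These counts therefore do not give the rate of false calls where arrays differ in such ways. In a simulation of the 31 lists, a list shifted by 0.3 on the log2 scale was called and the 30 others were not. That was 1 run, with errors drawn independently for each probe and a shift above the median of every list called below. It therefore gives neither the rate of false calls among correlated genes nor the power at the list medians found.

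Alternatives covered the background correction, its offset, the normalization, the filter, the authors' processed values, the variance model, array weights, a plain t-test, averaging per gene, a replicate block, the list test and leaving out each array. A fit with the slide as a block was not run, since neither labels nor column names give slides. A correction for probe position, and a restriction to probes past base 1000 of their transcripts, were added after seeing the data. For arrays without bead numbers, the number of arrays limits the precision, with a median SD between arrays of 0.10 in room air and 0.08 in smoke on the log2 scale.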

Results

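The study asked how cigarette smoke reaching the young through their mother affects gene expression in the adult testis. Females were exposed through the nose to the smoke of 12 reference cigarettes per session, in 2 sessions of 60 minutes a day on 5 days a week. Exposure began 6 weeks before mating, lasted 12 to 18 weeks in all, and ended when the pups were weaned at 21 days. In total 27 females were exposed, and control females received room air. Testes of adult offspring were profiled on 6 arrays, 3 per group. The labels do not say which litters the mice came from, so p-values measure only the spread between these samples. The median unprocessed intensity per array lay between 149.2 and 167.9, and the brightest probe of each array between 16852 and 18902. The first principal component held 48.1% of the variance and separated the 3 smoke arrays from the 3 room-air arrays.

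The extraction text in the labels names ovaries, whereas every other label says testis. Protamine 1 (Prm1) and transition protein 1 (Tnp1), which package sperm DNA, were brighter than 99.9% and 98.8% of all probes. Insl3, a hormone of Leydig cells, was brighter than 98.0%. Of the ovary genes, Zp2, Zp3, Bmp15, Oosp1, Nobox and Foxl2 were not above background in either group, and Zp1 was not in smoke. Nlrp5, Figla and Cyp19a1 were above background in both groups, at the 60.6th, 54.7th and 52.5th percentiles of intensity, and Gdf9, at the 86.0th, and Nlrp14, at the 99.5th, were bright on all arrays. Of 9 Y-linked genes Ddx3y, Eif2s3y, Uty, Usp9y, Zfy1 and Rbmy were above background in both groups, and Sry and Zfy2 in neither. Kdm5d was not above background in smoke, although its mean unprocessed intensity was 153.2 there and 149.8 in room air. Xist, between 140.5 and 156.3 units of intensity, was not above background in room air. In smoke Xist was not under the median on every array, so by the same rule it counted as above background. Clu had no probe under that symbol.

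In testes of smoke-exposed offspring, genes with large increases included Wfdc15b, Spink8, Defb38, Defb28 and Cd52. Angptl7 and, at its named probe alone, Ybx2 were among those with large decreases. The order by size depended on the background correction. Spink8, a serine protease inhibitor, rose 6.25-fold (log2 change 2.64 ± 0.08 SE, n = 3 per group, limma adjusted p = 5.5e-09). Cd52, a surface glycoprotein of lymphocytes and of sperm in the epididymis, rose 5.63-fold (2.49 ± 0.08, adjusted p = 5.5e-09 with limma). The beta-defensins Defb38, Defb28 and Defb37, which are antimicrobial peptides, were not above background in room air and rose at least 3.87-fold, 4.35-fold and 2.07-fold after background correction, against ratios of 2.29, 2.41 and 1.51 in the authors' processed values. Angptl7, a secreted angiopoietin-like protein, fell at least 3.10-fold after background correction (1.91-fold in the authors' values) and was not above background in smoke. Ybx2, a Y-box protein that binds stored mRNA in germ cells, fell 2.32-fold at its named probe, at base 61 of the transcript. Its second probe, at base 1476, did not pass (log2 change -0.07 ± 0.08 SE).

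Of 12848 probes tested, 852 passed an adjusted p of 0.05 with limma and Benjamini-Hochberg adjustment, 458 of them higher and 394 lower in smoke. They represent 799 named genes, and their median absolute log2 change was 0.38. In all 852 the 3 smoke arrays lay on one side of the 3 room-air arrays, as they did for 28.5% of all tested probes, where chance gives 10%. At an unadjusted p under 0.05 there were 3102 probes, against 642 expected by chance, and 86 of these changed by at least 1.5-fold, 48 higher and 38 lower, all 86 of which also passed the adjusted threshold. The count of 852 became 553, 702 and 337 without room-air arrays 1, 2 and 3, and 410, 304 and 369 without smoke arrays 1, 2 and 3.

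Among the other genes that rose, Wfdc15b, which encodes a small secreted protein of the WAP family, was not above background in room air and rose at least 5.55-fold after background correction (2.81-fold in the authors' values; mean log2 intensity 6.30 ± 0.11 in room air and 9.15 ± 0.11 in smoke, SD, n = 3). Its probe lies on chromosome 2 at 164040869 to 164040918 and that of Spink8 on chromosome 9 at 109729011 to 109729060, in the unnamed build of the deposited table. Crisp1, a secretory protein of the epididymis that coats sperm, rose at least 2.01-fold after background correction (1.58-fold in the authors' values; log2 intensity 5.86 ± 0.02 in room air and 7.69 ± 0.02 in smoke, SD, n = 3). Both genes had a second, dimmer probe outside the 12848. In a limma fit of all probes that of Crisp1 did not pass (log2 change -0.07 ± 0.09 SE), and that of Wfdc15b was higher (adjusted p = 6.9e-05), with mean unprocessed intensities of 121 in room air and 180 in smoke. Cstdc2, of the cystatin family, rose 3.51-fold, Cuzd1 3.04-fold, and Cfd, the complement protease adipsin, 3.04-fold. For the 10 genes most raised the limma adjusted p lay between 5.5e-09 and 3.9e-07.

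Epididymal genes were measured as a sign of neighbouring tissue. Of 11 genes of that list on the array, Crisp1 and Adam7 rose over all probes, and 9 did not pass. Adam7, a membrane protein of the epididymis, rose at least 1.89-fold after background correction (log2 change as measured 1.48 ± 0.07 SE, n = 3 per group, limma adjusted p = 3.4e-07). In the authors' values its log2 change was 0.55. Lcn5, Lcn8, Lcn9, Gpx5, Wfdc2, Spint4 and Teddm1a were not above background in either group. Cst8 (log2 change -0.05) and Cst11 (0.13) were above background and did not pass. Only 4 of the list's genes were bright enough to be tested, so the list itself was not. Both tested members that passed also passed adjusted over the list alone.

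**Figure D1:**
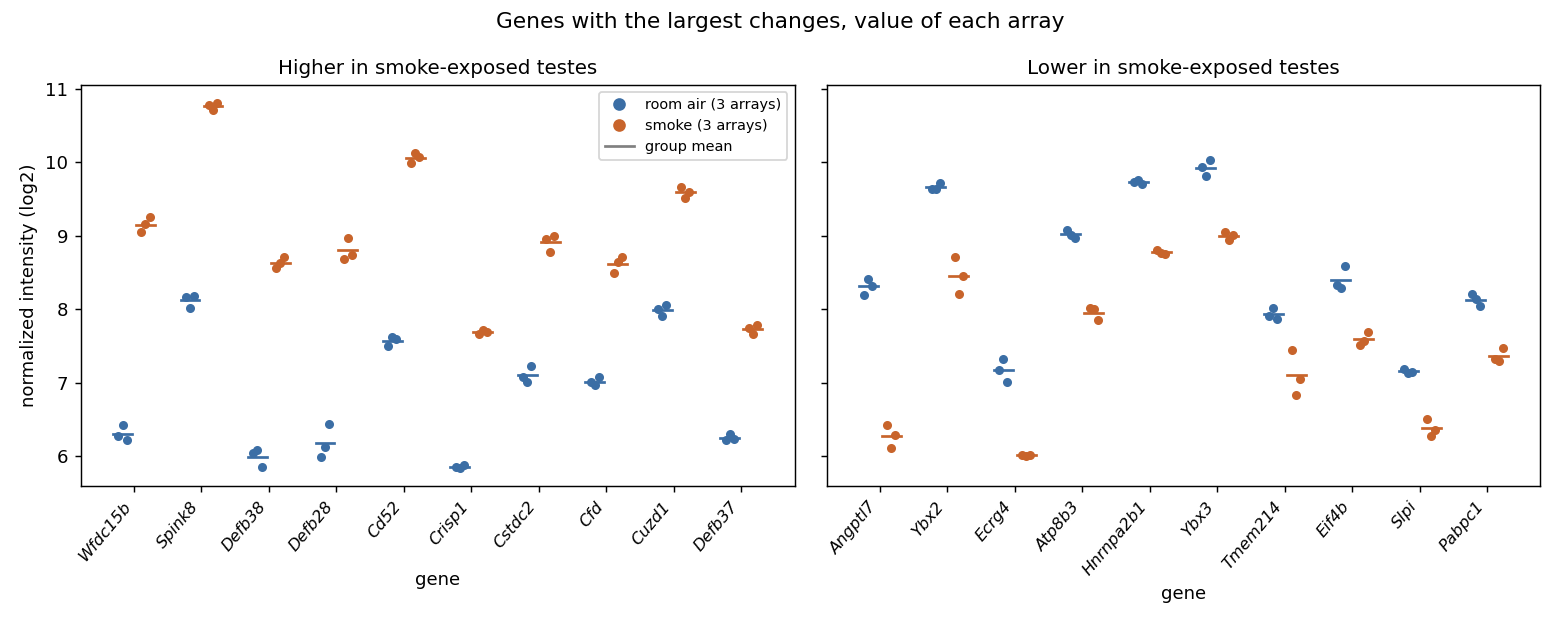
Normalized log2 intensity (vertical axis) of the 10 genes most raised (left) and the 10 most lowered (right) in smoke, with each point 1 array and each line the mean of 3 arrays. The 3 smoke arrays of Spink8 have a mean of 10.76 against 8.12 in room air, and those of Angptl7 6.27 against 8.31.

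At their named probes, Ybx2 fell by 1.21 ± 0.11 on the log2 scale (SE, n = 3 per group, limma adjusted p = 0.000144), Ybx3 by 0.93 ± 0.08, Hnrnpa2b1 by 0.95 ± 0.07, the translation initiation factor Eif4b by 0.81 ± 0.09 and the poly(A)-binding protein Pabpc1 by 0.77 ± 0.08. Atp8b3, a phospholipid-transporting ATPase of sperm, fell 2.09-fold, and Tmem214 1.77-fold. Ecrg4 and the protease inhibitor Slpi were not above background in smoke and fell at least 1.40-fold and 1.39-fold after background correction. For the 10 genes most lowered, Angptl7 included, the limma adjusted p lay between 2.8e-07 and 0.00524.

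Most of these genes had other probes that did not pass. The second Ybx2 probe, at base 1476 of the transcript against base 61 for the named one, changed by -0.07 ± 0.08 (SE). The further probes of Atp8b3 changed by -0.01 at base 35, upstream of the named probe at base 274, by 0.04 at base 3960 and by -0.09 at base 4131, the brighter of 2 further Hnrnpa2b1 probes by 0.17, that of Tmem214 by -0.13, and those of Ybx3 by -0.21 and -0.31. Of the Pabpc1 probes, that at base 456 fell by 0.52, and that at base 2200 changed by -0.05.

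Probe position, examined after the values were seen, went with direction across the array. The 38 probes lower by at least 1.5-fold had a median start at base 404.5, the 48 higher ones at base 1667.5, and all tested probes at base 1721. In the first 250 bases of transcripts 10.1% of probes were called lower and 2.45% higher, and past base 4000 the shares were 0.826% and 6.54%. Transcript length was not taken into account, so these shares mix probe position with the length of the transcript. The first and the last tested probe of each transcript were compared where they lay over 100 bases apart. Of 13 such pairs with a probe lower by 1.5-fold, the upstream probe was the lower one in 13, as it was in 4 of 5 pairs with a probe higher by 1.5-fold and in 64.7% of all 1377 pairs. With every pair of probes counted, 15 transcripts held a probe lower by 1.5-fold, and in 2 of them, Atp8b3 and Mdm1, a less lowered probe lay upstream of it. In Akap4, a structural protein of the sperm tail, the upstream probe fell by 0.70 ± 0.08 and the downstream probe changed by 0.16 ± 0.08. The pairs of Odf2, an outer dense fibre protein, and of Chka, Rexo5, Nt5c2 and Arl14ep likewise held a lower upstream probe and a downstream probe within 0.06 of 0.

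**Figure D2:**
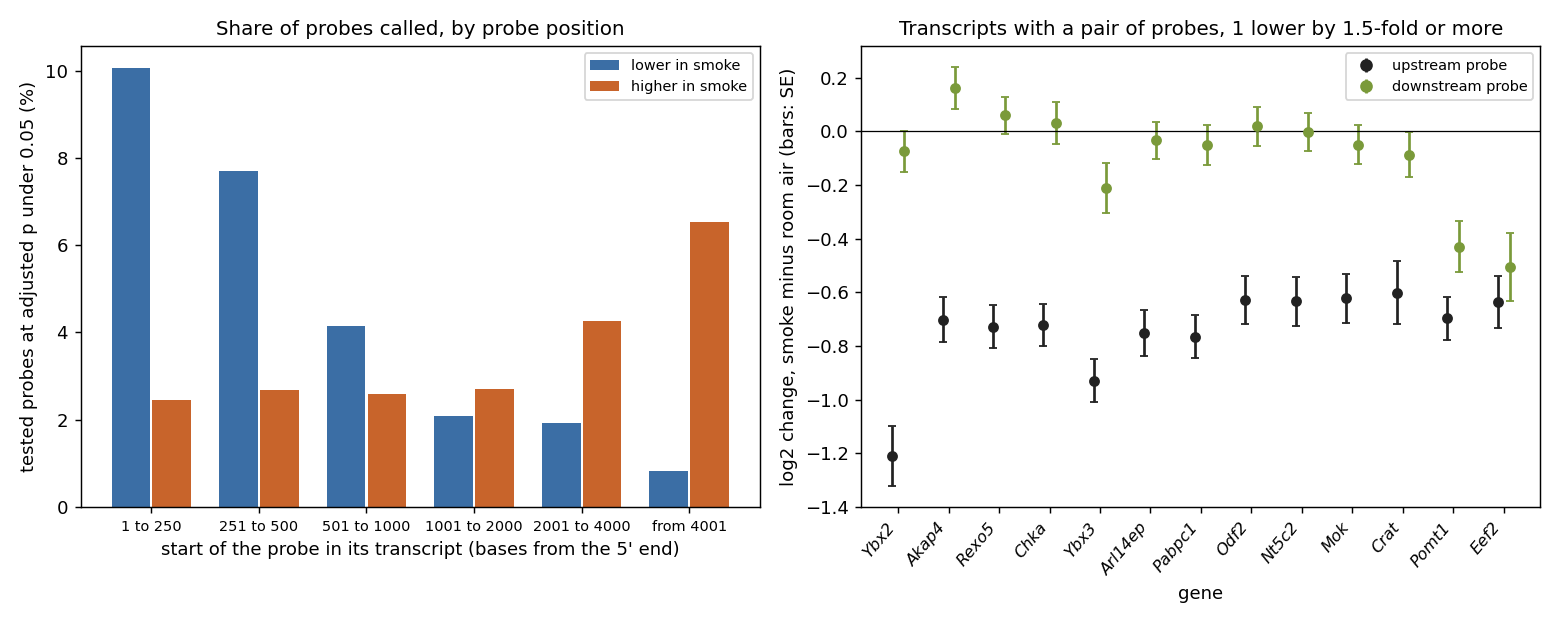
Left, percentage of tested probes called lower or higher in smoke, by the start of the probe in its transcript. Right, log2 change of the upstream and the downstream probe, with SE bars, in the 13 transcripts whose first or last probe was lower by at least 1.5-fold; the upstream probe of Ybx2 stands at -1.21 and the downstream one at -0.07.

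Of 31 gene lists tested, 13 passed with fry and Benjamini-Hochberg adjustment, 12 higher and 1 lower. With camera and a preset correlation 6 passed, namely Leydig cells, glutathione S-transferases, cholesterol synthesis, barrier junctions, Sertoli cells and peritubular cells, and with an estimated correlation none did. With single arrays left out, fry called 9, 4 and 2 lists without room-air arrays 1, 2 and 3, and 3, 1 and 3 without smoke arrays 1, 2 and 3. Lists not among the 13 that passed with an array left out were the round spermatid, Y-linked and immediate early lists without room-air array 1 (fry adjusted p = 0.0242, 0.0171 and 0.00645) and DNA repair without smoke array 1 (0.0486).

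Of 13 measured Leydig cell and steroidogenesis genes 5 rose, none fell and 8 did not pass, and 7 rose adjusted over the list alone. The prolactin receptor Prlr rose 1.98-fold, the luteinizing hormone receptor Lhcgr 1.73-fold, and the steroid-making enzymes Cyp17a1 and Cyp11a1 1.67-fold and 1.54-fold. Their log2 changes were 0.98 ± 0.09, 0.79 ± 0.07, 0.74 ± 0.07 and 0.63 ± 0.08 (SE, n = 3 per group), while a second Lhcgr probe, at base 2352 against base 2215, stood at 0.36 ± 0.11 and did not pass. The list's median was 0.21 (fry adjusted p = 0.00942, and adjusted p = 0.407 with an estimated correlation), and without smoke array 2 it did not pass (fry adjusted p = 0.0642). Insl3 changed by 0.31 and Tspo by -0.02, neither past the threshold over all probes.

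Enzymes of cholesterol synthesis, which supplies the substrate of steroid hormones, passed the list test as higher (adjusted p = 0.407 with camera at an estimated correlation). Of 15 measured genes 5 rose and 10 did not pass, and 6 rose adjusted over the list alone. Dhcr7 rose 1.57-fold (log2 change 0.65 ± 0.09 SE), Msmo1 1.39-fold (0.48 ± 0.09) and Insig1, a regulator that restrains the pathway, 1.26-fold (0.33 ± 0.07), a call lost in 4 of 19 alternatives. Cyp51 (-0.13) and Sqle (-0.11) did not pass. The median was 0.14 (fry adjusted p = 0.00478).

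Of 13 blood-testis barrier genes 3 rose, and of 14 Sertoli cell genes 1 did. F11r, Cldn3 and Espn, of the barrier list, rose 1.39-fold, 1.37-fold and 1.35-fold at their probes of highest mean. The Espn call was lost in 3 of 20 alternatives, and a second Espn probe rose 1.68-fold. In all, 10 of 13 barrier genes did not pass, while 5 rose adjusted over the list alone, among them Nectin2 (log2 change 0.32 ± 0.09 SE). The barrier median was 0.21 (fry adjusted p = 0.0418, and adjusted p = 0.493 with an estimated correlation). Of 14 Sertoli genes 13 had a change above 0, and Trf, transferrin, rose 1.34-fold, over all probes and adjusted over the list alone, a call lost in 13 of 19 alternatives, among them every array left out but smoke array 2. The Sertoli median was 0.17 (fry adjusted p = 0.0418, and adjusted p = 0.493 with an estimated correlation). All 8 peritubular and smooth muscle genes had a change above 0 with none past the threshold over all probes, and Smtn, Acta2 and Myh11 passed adjusted over the list alone (median 0.16, fry adjusted p = 0.0418, and adjusted p = 0.493 with an estimated correlation). Under median scaling the Sertoli, barrier and peritubular lists did not pass, nor did they without room-air array 2 or 3 or any smoke array, and the peritubular list also not without room-air array 1.

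Glutathione S-transferases, which conjugate reactive compounds to glutathione, rose in 5 of 17 genes and fell in none, and 9 rose and 1 fell adjusted over the list alone. Gsta3 rose 1.47-fold (log2 change 0.55 ± 0.09 SE), Gstm1 1.40-fold (0.49 ± 0.07), Mgst2 1.37-fold and Mgst1 1.32-fold, the last a call lost in 4 of 19 alternatives. The median was 0.19 (fry adjusted p = 0.0397, and adjusted p = 0.514 with an estimated correlation). Among 21 antioxidant enzymes only Gpx3, a secreted glutathione peroxidase, rose, 1.58-fold (0.66 ± 0.08), over all probes and adjusted over the list alone (list median 0.06, fry adjusted p = 0.0397, and adjusted p = 0.550 with an estimated correlation). Both calls were lost without room-air array 3 or any smoke array, and that of the transferases also without room-air array 1.

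In the list of the aryl hydrocarbon receptor, which senses combustion products, 2 of 5 genes rose and 3 did not pass. Ugt1a6a rose 1.47-fold and Aldh3a1 1.39-fold, over all probes and adjusted over the list alone. The Aldh3a1 call was lost in 2 of 19 alternatives. Arnt and Cyp1b1 (log2 change -0.11 ± 0.11 SE) did not pass. The median was -0.10, the mean 0.13 and the fry direction higher (adjusted p = 0.0484, and adjusted p = 0.825 with an estimated correlation). The call was lost without any single array. Cyp1a1 and Tiparp were not above background in either group. Ahrr, in a fit of all probes, changed by 0.18 and did not pass.

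Of 17 genes of meiotic spermatocytes, Sycp1, of the synaptonemal complex, fell by 0.58 ± 0.13 (SE) on the log2 scale and Hormad2 fell 1.31-fold, both also adjusted over the list alone, and 15 did not pass (median -0.06, fry adjusted p = 0.0424, and adjusted p = 0.514 with an estimated correlation). That list did not pass with any single array left out. At the probe of highest mean, none of 9 spermatogonial genes (median 0.07, fry adjusted p = 0.0591), 15 round spermatid genes (-0.04, fry adjusted p = 0.195) or 17 elongating spermatid genes (0.04, fry adjusted p = 0.202) passed over all probes. Upstream probes of Akap4 and Odf2, both of the elongating spermatid list, did pass, falling by 0.70 and 0.63. Values of smallest p were Uchl1 0.21 and Etv5 0.22, Zpbp -0.20 and Adam3 0.16, and Akap3 0.16 and Tnp2 0.20. In the flagellum list Dnah8 rose by 0.35 among 15 genes (fry adjusted p = 0.195), and in the piRNA list Mov10l1 rose by 0.29 among 10 (fry adjusted p = 0.203), each also adjusted over the list alone. The calls of Mov10l1, Dnah8, Hormad2 and Sycp1 were lost in 13 of 20, 10 of 20, 9 of 19 and 5 of 20 alternatives, that of Sycp1 without room-air array 3 or any smoke array.

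Other cells and the matrix gave mixed results. In the extracellular matrix list 3 of 19 genes rose, 2 fell and 14 did not pass. Timp2 rose 1.44-fold, Col4a2 1.38-fold and Timp3 1.35-fold (lost in 5 of 20 alternatives), while the collagenase Mmp2 fell 1.46-fold. Adjusted over the matrix list alone, 6 of its genes rose and 4 fell. The matrix list had a median of -0.02, a mean of 0.03 and a fry direction of higher (adjusted p = 0.0484, and adjusted p = 0.832 with an estimated correlation). Of 9 endothelial genes Vwf rose 1.34-fold and Cldn5 1.42-fold, calls lost in 2 of 19 and 4 of 19 alternatives, with Esam also passing adjusted over the list alone (median 0.08, fry adjusted p = 0.0484, and adjusted p = 0.514 with an estimated correlation). Of 16 leukocyte genes Fcer1g rose by 0.30, a call lost in 12 of 18 alternatives, while adjusted over the list alone 3 rose and 3 fell, among them Cd74 at -0.26, H2-Aa at -0.29 and C1qb at 0.26 (fry adjusted p = 0.404). Of 7 inflammatory genes the chemokine Cxcl12 rose 1.36-fold, also adjusted over the list alone, a call lost in 3 of 20 alternatives (list median 0.11, fry adjusted p = 0.0491, and adjusted p = 0.514 with an estimated correlation). Among 3 red blood cell genes Hba-a1 changed by 0.25 and Alas2 by -0.01, and neither passed. The matrix and inflammatory calls were lost without any single array, and the endothelial call without each array other than smoke array 3, with the position trend removed and past base 1000.

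Of 20 apoptosis genes none passed, over all probes or adjusted over the list alone, with Casp8 at 0.25 and Trp53 at 0.24 (median 0.05, fry adjusted p = 0.0395, and adjusted p = 0.650 with an estimated correlation). That call was lost without room-air array 2 or 3 or any smoke array. None of 29 DNA repair genes (fry adjusted p = 0.330), 35 genes of oxidative phosphorylation (0.562), 14 of mitochondrial DNA maintenance (0.746) or 24 ribosomal protein genes (0.803) passed over all probes. Rad50 stood at 0.25 and Parp1 at 0.20, Ndufa4 at 0.23 and Atp5c1 at -0.17, Twnk at -0.25 and Tfb1m at -0.25, and Rpl4 at -0.16 and Rps9 at -0.10. Hspa8 fell by 0.60 ± 0.09 at a probe starting at base 25 of its transcript, and Hspd1, at 0.30, passed adjusted over the list alone (17 heat shock genes, fry adjusted p = 0.547). Calr fell by 0.55, a call lost in 6 of 19 alternatives, and Pdia4, at 0.28, passed adjusted over the list alone (12 genes of the unfolded protein response, fry adjusted p = 0.957).

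Among 19 chromatin modifiers the deacetylase Hdac6 rose by 0.38 ± 0.07 and the histone methyltransferase Ezh2 fell by 0.35 ± 0.08 (SE), both also adjusted over the list alone, calls lost in 4 of 19 and 6 of 19 alternatives (fry adjusted p = 0.998). Of 7 imprinted genes Igf2 rose by 0.32 ± 0.09, also adjusted over the list alone, a call lost in 14 of 20 alternatives and without any single array (fry adjusted p = 0.404). Zfp36 rose by 0.35, a call lost in 4 of 19 alternatives, and Dusp1, at -0.25, passed adjusted over the list alone among 7 immediate early genes (fry adjusted p = 0.132). Of 9 interferon genes none passed, with Oasl2 at 0.24 and Bst2 at -0.29 (fry adjusted p = 0.290). Of 6 Y-linked genes Ddx3y rose by 0.36, a call lost in 8 of 19 alternatives, while adjusted over the list alone Usp9y at 0.30 and Rbmy at 0.21 also passed (fry adjusted p = 0.0591). Of 5 genes of the ovary list none passed over all probes, and Figla, at 0.25, passed adjusted over the list alone (fry adjusted p = 0.825).

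**Figure D3:**
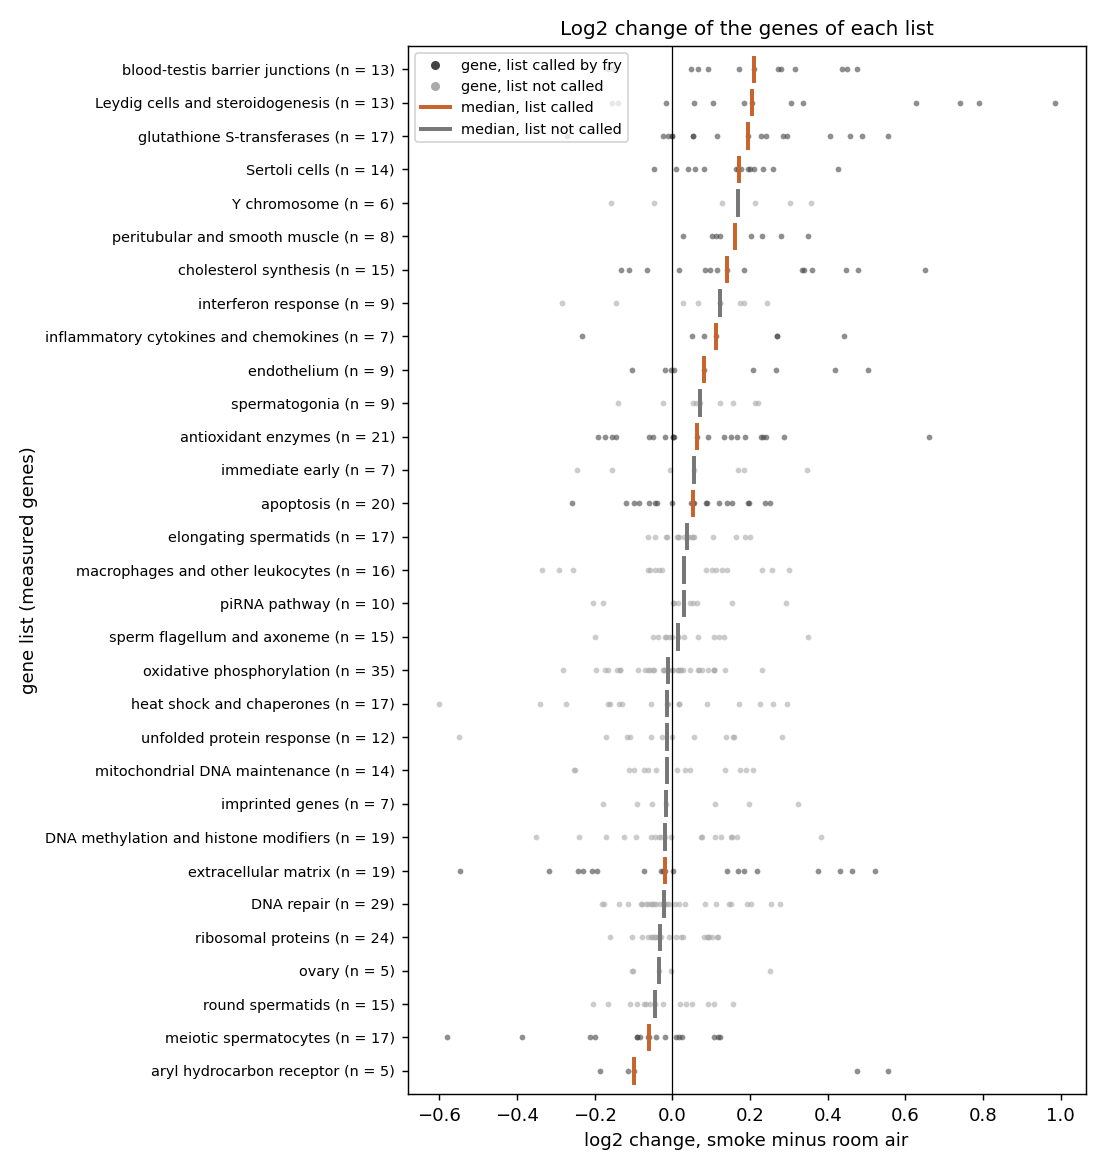
Log2 change, smoke minus room air, of each measured gene (points) and the median (bar) of the 31 tested gene lists, with lists called by fry in dark points and orange bars. The medians run from -0.10 for aryl hydrocarbon receptor targets to 0.21 for barrier junctions.

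The authors' deposited list holds 24 probes, 18 higher and 6 lower in smoke. All 24 passed in the limma fit with the same sign, and 16 had an adjusted p under 0.05 in the deposited table. The highest deposited ratios were those of Spink8 at 4.08, Cd52 at 3.35, Wfdc15b at 2.81, Defb28 at 2.41 and Defb38 at 2.29. The lowest were those of Angptl7 at 0.524, Ybx2 at 0.540, Ybx3 at 0.597, Hnrnpa2b1 at 0.602 and Atp8b3 at 0.622. The whole deposited table holds 45 probes with an adjusted p under 0.05, 29 higher and 16 lower. Across 12809 tested probes the deposited and the recomputed log2 changes had a Pearson r of 0.961, and the recomputed change was 1.42 times the deposited one by regression; probes are not independent replicates. In the deposited enrichment table the term of smallest p was defense response to bacterium, with 3 listed genes of 76 in the term.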

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

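The 2 tests by probe position were chosen after the result was seen, and all other settings before the data were examined. None of the 852 called probes turned sign in any alternative that tested single probes. The count fell to 547 with no filter on dim probes, to 72 with a plain t-test and to 460 with probes past base 1000, where fewer probes were tested. It rose to 1127 with no background correction, 1161 in the authors' processed values, 1180 with a trended and robust variance model and 1185 with array weights. The 458 higher and 394 lower became 316 and 144 past base 1000, 456 and 302 averaged per gene, and 296 and 317 with median scaling. The 86 probes past unadjusted p 0.05 and 1.5-fold became 57 with no background correction, 146 with an offset of 16, 33 in the brightest 25%, 24 in the authors' processed values and 40 past base 1000. The 13 lists became 4 with median scaling, 8 with cyclic loess, 5 in the brightest 25%, 8 past base 1000, 6 and 0 with camera at a preset and an estimated correlation, and 27 with the test for change in either direction. The cause was not tested, apart from the smaller number of probes under stricter filters. Leaving out 1 array gave 304 to 702 probes (fewest without smoke array 2), 88 to 119 past 1.5-fold, and 1 to 9 lists. With the replicate block 570 probes, 86 past 1.5-fold and 5 lists passed. Deviations of arrays of the same number correlated at -0.08, 0.02 and 0.00, which gives no sign that the numbers pair the samples. Shared handling of arrays of the same number cannot be excluded this way. The apoptosis median turned to -0.00020 in the brightest 25% of probes. Of 1120 values of the 59 called genes among the 106 named under other settings, 968 stayed past the threshold, 152 did not and 0 turned. Some calls given above without a count of lost alternatives were lost with the plain t-test alone. Among these were Prlr, Cyp11a1, Dhcr7, Gpx3, Gstm1, Gsta3, Ugt1a6a and Hspa8. Cholesterol synthesis passed fry in all 19 alternatives and the Leydig list in 18. With the position trend removed 775 probes passed, 730 of them among the 852, and 10 lists, without the matrix, endothelial and aryl hydrocarbon receptor lists. Signal over background limits the folds of the dimmest genes: Crisp1 ran from 0.66 in the authors' values to 2.85 at an offset of 16.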

Other observations

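The tests in this part were chosen after the values were seen, except the count over splits of the arrays. Gene families were formed from shared symbol stems with at least 5 measured genes, 289 in all, of which 30 passed fry with Benjamini-Hochberg adjustment. No family passed camera with an estimated correlation (adjusted p = 0.928 for each family named here). Aldehyde dehydrogenases, which oxidise reactive aldehydes, rose in 6 of 15 genes and fell in none (median 0.23, fry adjusted p = 0.0208), with Aldh2 up 1.44-fold and Aldh1a7 up 1.47-fold. Tissue kallikreins rose in 6 of 12 genes and fell in 1, Klk1b22 (median 0.28, fry adjusted p = 0.0242), and their sequences are alike, so that probes may read more than 1 member, which was not tested. Of 6 chemokines of the Ccl stem 3 fell, the near-identical Ccl21a and Ccl21c by 0.69 and 0.58 and Ccl28 by 0.33 (fry adjusted p = 0.0375). Of 15 beta-defensins 6 rose and none fell (median 0.21, fry adjusted p = 0.00417). Defb21 rose by 0.49, Defb36 by 0.31 and Defb22 at least 1.49-fold after background correction. The others were Defb38, Defb28 and Defb37, named above. These and Defb22 were not above background in room air, so they passed the brightness filter through the smoke arrays, and any defensins dim in both groups were not counted. The family result thus largely repeats genes already seen to rise.

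Of 10 splits of the 6 arrays into 3 and 3, 1 called as many probes, the real one, with 852 against 0 as the highest of the others; so few splits cannot give a share under 0.05.

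Of 8 genes known from the epididymis that were higher in all 3 smoke arrays, Spink8 and Cd52 rose 6.25-fold and 5.63-fold. Defb28, Defb37, Defb38, Crisp1, Adam7 and Defb22 were not above background in room air, and their sizes depend on the correction. For these 8 genes background correction or normalization is argued against as the whole cause. Over 5 other corrections, scalings or the authors' values the lowest log2 change, that of Defb22 in the authors' values, was 0.38 and the highest limma adjusted p 0.000723. The genes were chosen for their rise on these same arrays, so the check bears on them alone and is no separate evidence of a rise. Carried-over epididymal tissue stays open, since 2 of 11 genes of the list fixed beforehand rose, and 7 of the 9 others were under the array median on all 6 arrays, where neither the sampled segment nor the function of those probes is known. An effect of the exposure on the testis itself also stays open and was not tested, as does a difference between litters.

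Where a transcript had a pair of tested probes, a probe lower by 1.5-fold was mostly the upstream one. Over 1377 transcripts with a pair of probes the upstream probe changed by a median of -0.064 against the downstream one, and the 3 smoke arrays lay below the 3 room-air arrays (difference of array medians -0.066 ± 0.017 SE, exact permutation p = 0.10, the smallest that 3 against 3 can give). This is consistent with signal lost towards the 5′ end in the smoke arrays, as a difference in RNA integrity could give. A change in transcript isoforms cannot be told apart from it: over 1197 pairs with no called probe the median was -0.043, which a shift of isoforms in many transcripts would give too. In Atp8b3 the probe at base 35 changed by -0.01 and that at base 274 by -1.06, the opposite order.

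The Leydig, Sertoli and barrier lists passed fry as higher, and none did with an estimated correlation (adjusted p = 0.407, 0.493 and 0.493); the Sertoli and barrier calls were also lost with median scaling and without 5 of the 6 arrays. With each array's average position trend removed, the medians were 0.19, 0.17 and 0.19 and the highest fry adjusted p was 0.0424. This argues against that average trend as the whole cause. The correction leaves in place position effects particular to single transcripts, so probe position otherwise stays open. A lower share of germ cells, which would raise all other cell types alike, cannot be told apart from a change in these cells. The mean over 40 genes of the 3 lists exceeded that over 8 peritubular genes by 0.039 ± 0.055 and over 9 endothelial genes by 0.066 ± 0.081 (SE over genes). Genes on the same arrays are not independent replicates, and the SE between arrays was 0.052 and 0.048. The mean of the 3 lists exceeded that over 16 leukocyte genes by 0.20 ± 0.06 (SE over genes, 0.025 between arrays), but the leukocyte genes went both ways. A change in the Leydig and Sertoli cells or in their number stays open too, with the exposure and the litter untested as its origin.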
